A study of Streptomyces venezuelae with 52 samples.

How the data were processed

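Total RNA of Streptomyces venezuelae was extracted with Trizol and bead beating and sequenced by MSR-seq, per the labels' protocols. MSR-seq is a tRNA sequencing method that reads base modifications from misincorporation by the reverse transcriptase. N1-methyladenosine (m1A) blocks Watson-Crick pairing, so that reads over it often carry another base. The labels name 4 strains, WT, Trm1L, Rmd1 and Rmd2, each under 3 treatments, Ctrl, EtOH (6% ethanol) and 42oC (42 °C), with 3 libraries per group. This set holds 36 libraries in 12 groups. A second set of 16 libraries in 8 groups, called the DM set here, holds WT under Ctrl, EtOH, 42oC and H2O, each labelled -DM or +DM, with 2 libraries per group. The labels do not expand Rmd1, Rmd2, DM or H2O. MSR-seq has an optional demethylase treatment, and DM is taken as the label of such a step only where this is said. The labels name both ISP2 and Glucose-Isoleucine medium for the series and do not give the medium of a single library.

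The authors aligned the reads to a curated tRNA reference and derived tRNA properties with a custom pipeline of Python and R scripts, per the series description. The labels name SAMtools with no version. The aligner, its settings and the source of the reference are not given in the sources used here. The authors deposited 52 files with values per reference position and 36 files with reads per reference, 1 of each per library where both exist. Per the file headers, the deposited position files hold counts of reads covering each position and counts of each base, of deletions and of insertions. They also hold a mutation value, which is a fraction that the authors computed. In at least 98.4% of the positions of every file the deposited fraction equalled the reads with a base other than the reference base over the coverage, within 0.0001. A further deposited column, the stop value, is a score of another kind: in at least 99.8% of the positions it equalled 1 minus the coverage at a position over the coverage at the next 3′ position. The tests used the deposited counts, not these columns. The files hold no charged and uncharged reads, so charging was not analysed here.

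The reference lists 58 sequences, of which 57 are tRNAs and 1 is a non-tRNA sequence of 116 nt. The reads of 4 pairs of identical tRNAs were summed, which left 53 tRNAs. Position 58 was taken as the adenosine that ends the last TTCRA motif (positions 54 to 58), which 52 tRNAs carry. Positions near the anticodon were counted from its first base, 34, found after a T. The mutated share at A58 is the percentage of reads with a base other than adenosine among reads with any base at that position. It follows m1A but is no stoichiometry, since the enzyme can read m1A as adenosine or stop at it. tRNAs are named by amino acid and anticodon, with a number where several genes share an anticodon. fMet-CAT is the initiator and Ile2-CAT the minor isoleucine tRNA.

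A58 was compared with edgeR's quasi-likelihood test on the pairs of mutated and unmutated reads, with an effect per library and an effect of mutated reads per group. A tRNA entered where every library of the set had at least 100 reads at A58: 51 tRNAs in the 36 libraries (24 residual degrees of freedom) and 49 in the DM set (8). Strains were compared with WT within each treatment, and treatments with Ctrl within each strain. Differences between a mutant's and WT's treatment effect were tested as interaction terms. P-values were adjusted by Benjamini-Hochberg within each comparison, and a tRNA was called at an adjusted p under 0.05. All tests were two-sided. The mean share over the 51 tRNAs was compared between groups by exact permutation tests, where 3 libraries against 3 cannot give a p below 0.1. Abundance was tested with edgeR's quasi-likelihood test on the deposited counts of reads per tRNA with TMM scaling and filterByExpr. Every position with coverage of at least 100 in all libraries and a mutated share of 5% or more in some group was scanned with the A58 model. Correlations across tRNAs used 100000 permutations.

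For 5 lists of tRNAs, fixed from names and sequences alone, limma's camera compared the list with the other tRNAs at a preset correlation of 0.01 and again with an estimated one. The lists are Leu, Ser and Tyr tRNAs (taken by amino acid as class II, with a long variable arm, which Leu-CAA of 78 nt lacks), anticodons beginning with T or A, adenosine at position 57, charged amino acids, and hydrophobic amino acids. The tRNAs named in each comparison are, by rule, the 10 with the largest rise and the 10 with the largest fall among called tRNAs whose libraries in the compared groups do not overlap. Leu-TAA, fMet-CAT and Arg-ACG are always included. Leu-TAA is the bldA tRNA, which reads the rare UUA codon. The main tests, lists, naming rule and alternatives were chosen before the data were examined. The test of Rmd2 at A59, the test of the base at position 59, the bootstrap interval and the counts over other splits were chosen after the results were seen.

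R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The models were tested on simulated data with 10 runs per comparison. Noise was drawn independently for each tRNA. Shifts shared by the tRNAs of a library were therefore not simulated, and the rates below do not cover them. Of shares changed by 0.5 on the log2 odds scale, 92% were called in a simulation of 42oC against Ctrl in WT over 51 tRNAs, and 94% in 1 of Rmd1 against WT. In the DM set, with 49 tRNAs, 10% were called at that size and 37% at a size of 1, so that the DM set sees large shifts only. For abundance of Trm1L against WT over 53 tRNAs, 91% were called at a log2 fold change of 0.5. Of the unchanged tRNAs 6.67% were called too, against 1.61% in each of the simulations of 42oC in WT and of Rmd1. The threshold concerns the share of false calls among calls, which was not computed, so some abundance calls may be false.

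Reads listed per library ranged from 4251542 to 9853800 in WT, 9588471 to 21992748 in Trm1L, 5036542 to 8737410 in Rmd1 and 10670003 to 19564034 in Rmd2. The position files of the DM set held 639066 to 1088928 reads near the 3′ end in the -DM libraries and 1564749 to 3276623 in the +DM libraries. The thinnest tRNA at A58 had 90 to 498 reads in a WT library and 1 to 20 in a -DM library, and tRNAs below the minimum were left out of the tests. Reads made by PCR are not independent molecules, so intervals from read counts cover counting error only. Between replicates, the reads per tRNA (in the DM set, those covering A58) varied by 52.5 to 3465 times what counting error alone gives (chi-square per degree of freedom). This was not computed for A58 shares, and the tests rest on the spread between libraries.

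Replicate numbers recur across groups. In 3 of 17 A58 comparisons every pair of libraries with the same number deviated together from its group means (correlation over 0.1): EtOH in Rmd1, and EtOH and 42oC in Rmd2. The same held for the abundance of Trm1L against WT. With the replicate number as a block, none of these counts moved by over 1.5 times. The labels do not say whether replicates are separate cultures, so that p-values may measure technical spread only. The labels of the files place each strain in 1 pool of its own, so strain and pool cannot be told apart. In the DM set each label fills 2 pools, 1 per replicate number, and no pool holds both labels. Alternatives covered the test, the coverage minimum, deletions and stops counted as mutated, the site, the replicate block, the groups in the model, the scaling of abundance, the site threshold, and leaving out each library in turn. The genes altered in the mutant strains are not tRNAs and were not analysed here, so no deletion was checked at the gene itself.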

Results

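The series asked how m1A in the tRNAs of Streptomyces venezuelae, a soil bacterium with a GC-rich genome, changes between strains and under stress, and its title names enzymes that erase m1A. Reads over 53 tRNAs were available from 36 libraries of WT, Trm1L, Rmd1 and Rmd2, each grown under Ctrl, EtOH (6% ethanol) and 42oC (42 °C) with 3 libraries per group. A second set of 16 WT libraries, with 2 per group, covered Ctrl, EtOH, 42oC and H2O, each labelled -DM or +DM.

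In WT under Ctrl, the adenosine at position 58 of the T loop, where bacterial TrmI enzymes place m1A, was misread in most tRNAs, at levels that spanned the whole scale. Of 52 tRNAs, 15 had a mutated share of 75% or more, 25 lay between 5% and 75%, and 12 lay under 5%, of which 8 were under 1%. The median was 42.9%. Ala-GGC-1 stood at 97.47% ± 0.0742, Thr-GGT-2 at 97.4% ± 0.166 and Lys-CTT at 93.1% ± 0.211 (SD, n = 3 each). The bldA tRNA Leu-TAA stood at 73.4% ± 0.625, the initiator fMet-CAT at 38.8% ± 0.866 and Arg-ACG at 22.8% ± 0.752 (SD, n = 3 each). Misread A58 was read as T in 60.02% ± 0.351, as G in 38.5% ± 0.352 and as C in 1.45% ± 0.0257 of the substitutions (SD, n = 3), over the 40 tRNAs with a share of 5% or more. At 457 other adenosines of the tRNAs the median share was 0.238% in the same libraries.

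In Trm1L the A58 signal was gone. Ala-GGC-1 fell from 97.47% to 0.284% ± 0.0095 (SD, n = 3; log2 odds −13.7 ± 0.102 SE, adjusted p = 7.37e-41), Leu-TAA from 73.4% to 0.194% ± 0.0334 (−10.49 ± 0.151 SE, 2.45e-33) and fMet-CAT from 38.8% to 0.231% ± 0.00989 (−8.10 ± 0.099 SE, 2.76e-35). Arg-ACG fell from 22.8% to 0.0714% ± 0.00399 (−8.69 ± 0.0916 SE, 4.93e-37). Across 52 tRNAs the shares in Trm1L under Ctrl lay between 0.0375% and 0.412%, with a median of 0.190%, against 0.234% at the other adenosines of the same libraries. Of 51 tRNAs tested, 50 fell under Ctrl, 49 under EtOH and 50 under 42oC, and none rose by edgeR's test. Glu-TTC had no call under any of the 3 treatments and Ser-GGA none under EtOH, both named here after their values were seen. Glu-TTC stood at 0.290% in WT under Ctrl. The libraries of both strains did not overlap for 49 tRNAs under Ctrl, where chance gives 10%. Each of the 9 Trm1L libraries had read-through, the coverage near the 5′ end over that near the 3′ end, of 72.1% to 78.5%, beside 74.7% to 80.9% in WT.

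In Rmd2 the opposite happened: A58 rose across nearly the whole tRNA set. Arg-CCG rose from 23.6% ± 1.16 to 74.2% ± 0.572 (SD, n = 3 each; log2 odds 3.22 ± 0.0843 SE, adjusted p = 5.44e-25) and Arg-ACG, which reads the arginine codons CGU, CGC and CGA through inosine, from 22.8% ± 0.752 to 71.9% ± 0.928 (3.12 ± 0.0802 SE, 5.44e-25). All 3 proline tRNAs rose, Pro-GGG from 20.4% to 60.9%, Pro-CGG from 29.2% to 67.2% and Pro-TGG from 28.04% to 64.6%. Both isoleucine tRNAs did so too, Ile-GAT from 22.3% to 56.0% and Ile2-CAT from 54.3% to 85.0%. Gln-CTG-2 rose from 44.6% to 83.4%, His-GTG from 25.2% to 53.5% and fMet-CAT from 38.8% to 66.3% ± 1.06 (SD, n = 3; 1.63 ± 0.0852 SE, 2.37e-17). Leu-TAA, already high in WT, rose from 73.4% to 84.3% ± 1.11 (SD, n = 3; 0.96 ± 0.12 SE, 9.39e-09). The same direction held under stress, where Arg-CCG stood at 75.2% against 24.1% under EtOH and at 75.4% against 23.5% under 42oC. Leu-TAA stood at 88.2% against 70.8% and at 91.6% against 78.9%, and fMet-CAT at 67.0% against 39.2% and at 67.3% against 40.1%.

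Of 51 tRNAs, 50 rose in Rmd2 under Ctrl, 51 under EtOH and 51 under 42oC. By edgeR's test none fell. Gly-CCC, named here after its values were seen, was the tRNA without a call under Ctrl, at 33.8% against 31.7% (adjusted p = 0.139). The median change under Ctrl was 1.29 on the log2 odds scale, and 33 tRNAs gained 5 points or more. Libraries of both strains did not overlap for 50 tRNAs under Ctrl, where chance gives 10%. Read-through was 82.9% to 85.8% in the Rmd2 libraries, above all WT libraries, and the strain and its pool cannot be told apart.

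**Figure D1:**
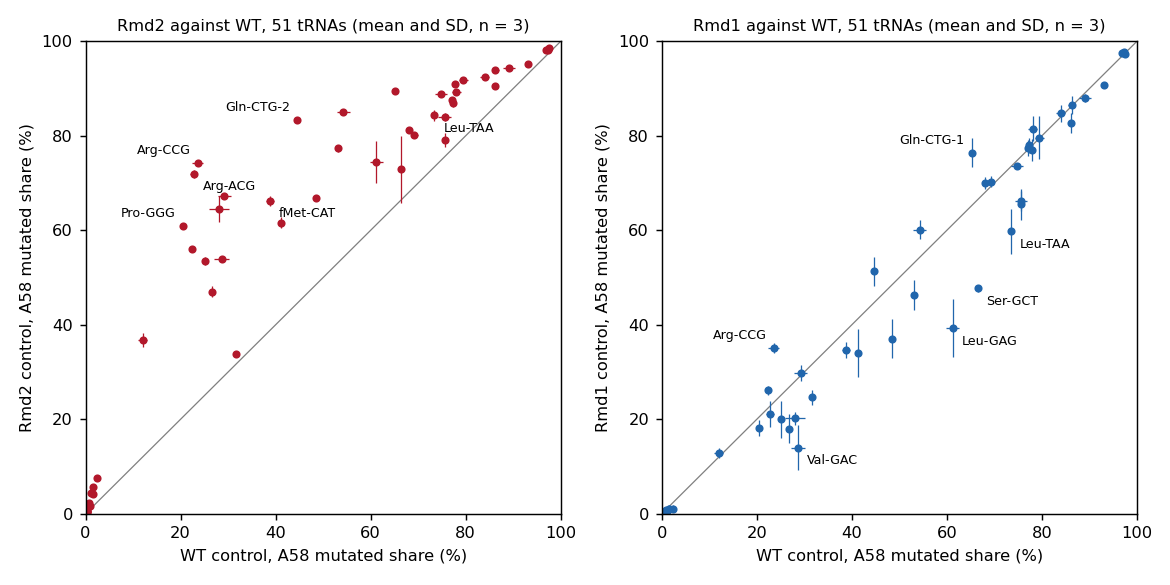
Mutated share at A58 (percent) of 51 tRNAs under Ctrl, WT on the horizontal axis against Rmd2 (left) and Rmd1 (right) on the vertical axis, as means with SD bars over 3 libraries each. In Rmd2 the points lie on or above the diagonal (50 called higher), while in Rmd1 they scatter to both sides (7 called higher, 27 lower).

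In Rmd1, A58 differed from WT in both directions. The balance of the counts differed between treatments, but this was not tested, and it turned under some alternatives given below. Under Ctrl, 27 of 51 tRNAs fell and 7 rose against WT. By 5 points or more, 13 fell and 4 rose, and 12 of the 51 lay under 5% in both strains. The median at other adenosines was lower in Rmd1 too, at 0.152% against 0.238% in WT. Leu-GAG fell from 61.2% ± 1.38 to 39.3% ± 6.16 (SD, n = 3 each; log2 odds −1.30 ± 0.176 SE, adjusted p = 1.7e-07) and Ser-GCT from 66.5% ± 0.517 to 47.7% ± 0.795 (−1.12 ± 0.134 SE, 2.55e-08). Val-GAC fell from 28.7% ± 1.54 to 13.99% ± 4.74, Leu-TAA from 73.4% ± 0.625 to 59.8% ± 4.71 (−0.89 ± 0.12 SE, 1.59e-07) and Leu-CAA from 48.6% ± 0.552 to 37.1% ± 4.18. Gly-TCC-1, Cys-GCA-2, Gln-TTG, Pro-TGG and Thr-TGT fell by 10.1, 9.37, 8.65, 7.87 and 7.2 points. fMet-CAT fell from 38.8% to 34.7% ± 1.62 (adjusted p = 0.00937), while Arg-ACG stood at 21.1% ± 2.77 (adjusted p = 0.0925). The rises were those of Arg-CCG from 23.6% to 35.1% ± 1.12 (0.81 ± 0.0829 SE, 2.06e-09), Gln-CTG-1 from 65.2% to 76.4% ± 3.04, Gln-CTG-2, Ile2-CAT and Ile-GAT among others.

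Under EtOH, 10 tRNAs were higher and 17 lower in Rmd1 than in WT, and under 42oC 17 were higher and 13 lower. Ser-GCT stayed below WT under stress, at 51.5% against 66.6% and at 51.7% against 66.7%. Arg-CCG stayed above it, at 38.5% against 24.1% and at 39.3% against 23.5%, as did Gln-CTG-1, at 79.5% against 67.4% and at 81.2% against 65.9%. Leu-TAA met the WT level under EtOH (70.1% against 70.8%, adjusted p = 0.754) and passed it under 42oC (82.7% against 78.9%, adjusted p = 0.0123). fMet-CAT stood at 35.9% against 39.2% (0.0491) and at 36.98% against 40.1% (0.0542), and Arg-ACG was not called (0.112 and 0.197). The groups' libraries did not overlap for 33, 34 and 32 tRNAs under Ctrl, EtOH and 42oC, where chance gives 10%. With deletions counted as mutated, the balance under EtOH turned to 17 higher and 11 lower, and without replicate 3 of Rmd1 under 42oC that under 42oC became 14 higher and 15 lower. Rmd1 libraries had a read-through of 35.2% to 48.6%, far below the 74.7% to 80.9% of WT, and strain and pool cannot be told apart.

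Averaged over the 51 tRNAs, the A58 share under Ctrl was 45.3% ± 0.0587 in WT, 0.182% ± 0.0018 in Trm1L, 43.1% ± 1.61 in Rmd1 and 59.5% ± 0.511 in Rmd2 (SD, n = 3 each). Under 42oC it was 47.6% ± 0.591 in WT, 48.7% ± 0.811 in Rmd1 and 62.6% ± 0.253 in Rmd2 (SD, n = 3 each). Of 17 exact permutation tests of these means, 15 gave the smallest p that 3 libraries against 3 allow, 0.1 (adjusted p = 0.113). The others were EtOH in WT (45.5% against 45.3%, exact p = 0.8, adjusted 0.8) and Rmd1 against WT under EtOH (45.9% against 45.5%, exact p = 0.5, adjusted 0.531). Weighted by coverage, EtOH in WT gave 49.9% against 48.9%, a difference of 1.0796 points beside 0.15521 for the plain mean. The weighted mean of Rmd1 lay below that of WT under all 3 treatments, at 43.7% against 48.9%, 47.4% against 49.9% and 50.04% against 51.3%, so that its position above WT under stress holds for the plain mean only.

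**Figure D2:**
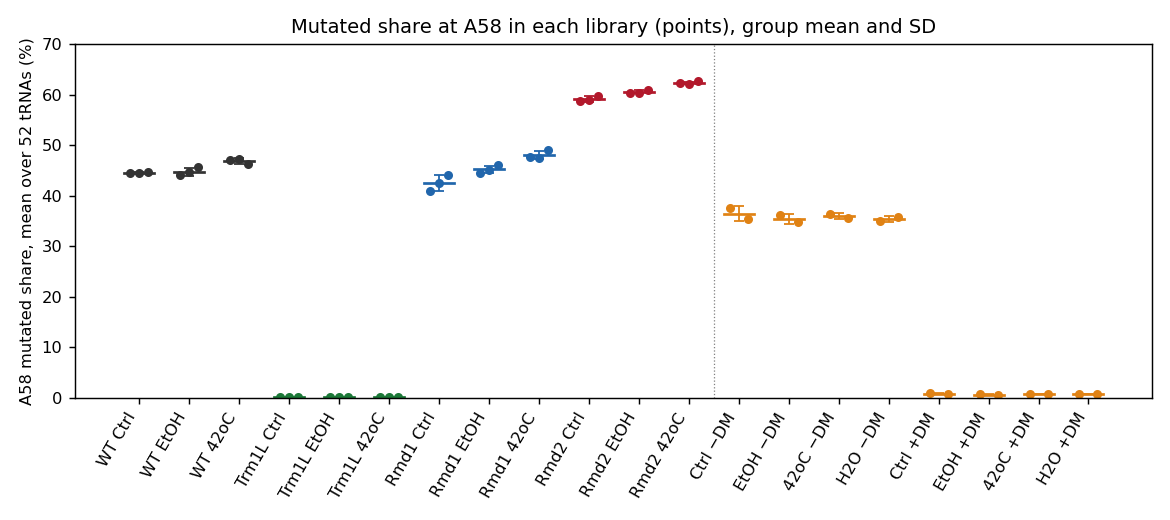
Mean mutated share at A58 over 52 tRNAs (percent) per library for the 20 groups of strain, treatment and DM label, with points for libraries and bars for the group mean and SD. Trm1L lies near 0 under all treatments, Rmd2 lies above WT at 59.1% under Ctrl, and the +DM libraries lie under 1%.

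In the WT set with 3 libraries per group, heat raised A58 for part of the tRNAs. Of 51 tRNAs, 20 rose at 42oC and none fell by edgeR's test (22 had an unadjusted p under 0.05). Of the 20, 9 gained 5 points or more. Arg-CCT, Val-CAC-1, Phe-GAA, Val-CAC-2, Tyr-GTA and Val-TAC were also among the 20. They stood between 1.48% (Arg-CCT) and 0.272% (Val-TAC) under Ctrl. The median at other adenosines was 0.238% under Ctrl and 0.252% at 42oC. Gly-TCC-1 rose from 75.6% ± 0.642 to 88.6% ± 2.3 (SD, n = 3 each; log2 odds 1.35 ± 0.121 SE, adjusted p = 2.64e-10) and Cys-GCA-2 from 75.6% ± 1.34 to 87.5% ± 0.87 (1.18 ± 0.124 SE, 4.74e-09). Leu-GAG rose from 61.2% to 73.7% ± 4.22, His-GTG from 25.2% to 36.6% ± 3.99 and Gly-CCC from 31.7% to 43.0% ± 3.81. Gln-TTG, Val-GAC, Asn-GTT-1 and Ala-TGC rose by 8.41, 7.13, 5.8 and 4.12 points. Leu-TAA rose from 73.4% to 78.9% ± 1.69 (0.44 ± 0.12 SE, 0.00306) and Arg-ACG from 22.8% to 25.5% ± 1.35 (adjusted p = 0.0294), while fMet-CAT stood at 40.1% ± 0.882 (adjusted p = 0.49). The libraries did not overlap for 26 tRNAs, where chance gives 10%.

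Ethanol moved few tRNAs in WT, 5 up and 4 down. Cys-GCA-2 fell from 75.6% ± 1.34 to 67.2% ± 2.48 (SD, n = 3 each; log2 odds −0.60 ± 0.114 SE, adjusted p = 0.000618) and Cys-GCA-1 from 12.01% to 9.75% ± 0.455. Val-CAC-2 and Phe-GAA, both near 1% or below, fell by 0.168 and 0.187 points. Both asparagine tRNAs rose, Asn-GTT-1 from 79.5% to 84.1% ± 0.971 and Asn-GTT-2 from 86.3% to 89.1% ± 0.681, with Arg-ACG (22.8% to 25.9%, adjusted p = 0.0336), Leu-CAG and Thr-GGT-1. Leu-TAA (70.8% ± 1.77, adjusted p = 0.381) and fMet-CAT (39.2% ± 1.42, adjusted p = 0.909) passed no threshold. The libraries did not overlap for 18 tRNAs, where chance gives 10%. The count of 9 fell to 1, 2 and 3 without replicate 1 or 3 of WT under Ctrl or replicate 3 of WT under EtOH, and the direction turned with the first and last of these, with 0 up and 1 down, and 1 up and 2 down. By limma 3 were up and none down, with only the groups compared 7 were up and 8 down, and with deletions counted 5 were up and 6 down, so that the balance has no firm direction.

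In Rmd1 both stresses raised A58 and lowered none by edgeR's test. At 42oC 38 of 51 tRNAs rose. Leu-GAG rose from 39.3% ± 6.16 to 71.9% ± 3.35 (SD, n = 3 each; log2 odds 2.00 ± 0.177 SE, adjusted p = 4.54e-11), Leu-TAA from 59.8% ± 4.71 to 82.7% ± 1.36 (1.68 ± 0.121 SE, 4.31e-13), Gly-TCC-1 from 65.5% to 87.6% and Cys-GCA-2 from 66.2% to 87.6%. Leu-CAA rose from 37.1% to 51.5%, His-GTG from 19.97% to 37.5% and Arg-ACG from 21.1% to 27.1%, while fMet-CAT stood at 36.98% (adjusted p = 0.129). Under EtOH 26 rose, among them Leu-GAG to 59.7% ± 3.24 (1.20 ± 0.176 SE, 4.5e-06), Leu-CAA to 48.0% ± 1.04, Leu-TAA to 70.1% ± 3.46 (0.66 ± 0.12 SE, 0.0001005) and Gly-TCC-1 to 74.9% ± 1.78. Arg-ACG stood at 23.97% (adjusted p = 0.013) and fMet-CAT at 35.9% (0.443). Libraries did not overlap for 36 tRNAs at 42oC and 19 under EtOH, where chance gives 10%. The EtOH count was 8 without replicate 1 of Rmd1 under Ctrl, the library with the lowest read-through (35.2%), 17 without replicate 3 of Rmd1 under EtOH, 17 by limma, and 3 with only the groups compared in the model.

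In Rmd2, 29 tRNAs rose at 42oC and none fell by edgeR's test. Gly-CCC rose from 33.8% ± 0.507 to 50.1% ± 0.568, His-GTG from 53.5% ± 0.897 to 69.3% ± 0.618 and Val-GAC from 53.98% ± 0.584 to 68.0% ± 0.94 (SD, n = 3 each). Cys-GCA-2 rose from 83.9% to 94.2% (log2 odds 1.65 ± 0.117 SE, adjusted p = 1.09e-12) and Leu-TAA from 84.3% to 91.6% (1.02 ± 0.12 SE, 2.35e-08). Arg-ACG stood at 73.5% (adjusted p = 0.192) and fMet-CAT at 67.3% (adjusted p = 0.498). Under EtOH 6 rose, with Leu-GAG from 74.5% to 82.2%, Leu-TAA from 84.3% to 88.2%, Gly-TCC-1, Cys-GCA-2 and Val-CAC-2 among them (adjusted p = 0.00856 each), and with fMet-CAT (0.695) and Arg-ACG (0.827) uncalled. Libraries did not overlap for 37 tRNAs at 42oC and 21 under EtOH, where chance gives 10%. The EtOH count was 1 without replicate 1 of Rmd2 under Ctrl, 0 without replicate 3 of Rmd2 under EtOH, 3 by limma, 10 with deletions counted and 15 with only the groups compared.

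In Trm1L, where A58 lay at background, stress moved 2 tRNAs in each condition by under 0.1 points. Ala-CGC (0.235% to 0.268%) and Gln-TTG (0.0963% to 0.159%) rose under EtOH, with an adjusted p of 0.0417 each. Lys-CTT (0.196% to 0.253%, adjusted p = 0.0136) and Thr-CGT (0.235% to 0.284%, adjusted p = 0.0177) rose at 42oC. The 42oC count was 11 by limma, 5 with deletions counted and 0 with only the groups compared, and leaving out single libraries gave 0 to 11. The replicate number as a block raised this count as well. Leu-TAA, fMet-CAT and Arg-ACG were not called, with adjusted p of 0.853, 0.706 and 0.676 under EtOH and 0.227, 0.711 and 0.243 at 42oC. The EtOH count was 0 without each of 5 of the 6 libraries.

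Most tRNAs that rose with heat in WT also rose in the mutants that keep A58. All 20 were called higher in Rmd1 as well, against 14.9 for independent lists of these sizes, and 18 in Rmd2, against 11.4. Across the 51 tRNAs, which are not independent replicates, the heat effects of WT and Rmd1 correlated with Spearman's rho 0.786 and Pearson's r 0.831, and those of WT and Rmd2 with rho 0.842 and r 0.905. These comparisons share no libraries. In both, the permutation p was 1e-05, the smallest that 100000 permutations can give (adjusted p = 2.25e-05 over 9 relations). The ethanol effects of WT and Rmd1 had a rho of 0.141 (permutation p = 0.319, adjusted 0.359), yet the 5 tRNAs called higher in WT, Asn-GTT-1, Asn-GTT-2, Arg-ACG, Leu-CAG and Thr-GGT-1, were all called higher in Rmd1, against 2.55 for independent lists. Between WT and Rmd2 the rho was −0.03 (permutation p = 0.849), with none of the 5 called in Rmd2, against 0.588. Between Rmd1 and Rmd2 ethanol effects correlated (rho 0.590, r 0.711, adjusted p = 2.25e-05), with 5 tRNAs called higher in both, against 3.06.

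Heat raised A58 by more in Rmd1 than in WT for 16 tRNAs. The excess was 1.24 ± 0.17 SE on the log2 odds scale for Leu-TAA (adjusted p = 2.43e-06), 1.17 ± 0.248 for Leu-GAG (0.00104) and 0.79 ± 0.114 for Leu-CAA (3.51e-06). These leucine tRNAs also fell against WT under Ctrl. Both comparisons use the same Ctrl libraries, so a low value of Rmd1 under Ctrl gives both. The same holds for the excess under EtOH. Under EtOH 16 tRNAs also exceeded the WT effect, with Leu-GAG at 1.10, Cys-GCA-2 at 0.96, Leu-TAA at 0.84 and Leu-CAA at 0.72 ± 0.114 SE (adjusted p = 3.21e-05). In Rmd2, 5 exceeded it under EtOH, led by Cys-GCA-2 (1.04 ± 0.159 SE, adjusted p = 1.78e-05) with Gly-CCC, Leu-TAA, Cys-GCA-1 and Val-CAC-2. At 42oC edgeR called no difference between Rmd2 and WT in the main model (8 at an unadjusted p under 0.05). Counting deletions gave 3, only the groups compared 1, the replicate block 2, and leaving out single libraries up to 2. Between Trm1L and WT, edgeR called none under EtOH in the main model (5 at an unadjusted p under 0.05), and limma called 1. By edgeR there were 4 with deletions counted, 2 with only the groups compared, 2 without replicate 1 of Trm1L under Ctrl and 1 with the replicate block. At 42oC edgeR called 7 in the main model, though A58 lay at background in Trm1L, so that a rise in WT alone gives a difference. Of these, 5 tRNAs rose in WT, among them Gly-TCC-1 (−1.06 ± 0.203 SE, adjusted p = 0.000764), and were not called in Trm1L. The other 2, Lys-CTT and Thr-CGT, rose in Trm1L (0.38 and 0.29, adjusted p = 0.0354 and 0.0371). For fMet-CAT and Arg-ACG no difference was called in any of the 6 comparisons, and Arg-ACG at 42oC in Rmd1 came nearest (0.27, adjusted p = 0.058). These counts rest on single libraries and on the model. That of Rmd1 under EtOH was 9 without replicate 1 of Rmd1 under Ctrl or replicate 3 under EtOH, 10 without replicate 1 of WT under EtOH and 8 with only the groups compared, and that at 42oC was 26 without replicate 3 of Rmd1 under Ctrl and 7 with only the groups compared. The count of 5 for Rmd2 under EtOH was 2 or 3 without any 1 of 7 libraries, 2 by limma, 10 with deletions counted and 14 with only the groups compared. The count of 7 for Trm1L at 42oC was 2 or 3 without any 1 of 5 libraries, 13 with deletions counted and 4 with only the groups compared.

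**Figure D3:**
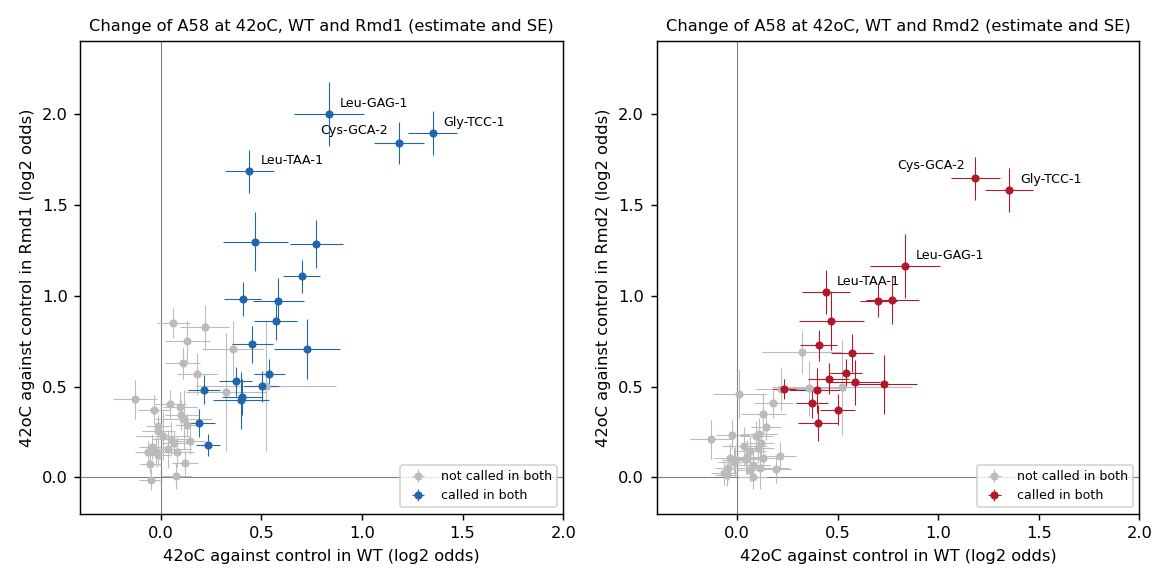
Change of the A58 mutated share at 42oC against Ctrl (log2 odds, estimate ± SE) for 51 tRNAs, WT on the horizontal axis against Rmd1 (left) and Rmd2 (right) on the vertical axis, with tRNAs called in both strains coloured. Called tRNAs lie at positive values on both axes, 20 with Rmd1 and 18 with Rmd2.

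None of the 5 lists of tRNAs was called against the other tRNAs in the A58 comparisons of the 36 libraries, the only ones in which lists were tested. Over all camera tests the lowest adjusted p was 0.203 with the preset correlation and 0.533 with an estimated correlation, so no call was made with either. In Rmd2 under Ctrl every tested member rose, 10 Leu, Ser and Tyr tRNAs (9 with a long variable arm, which Leu-CAA lacks), 13 with an anticodon beginning with T or A, 18 with adenosine at 57, 11 for charged and 21 for hydrophobic amino acids. In Rmd1 under Ctrl, 6 Leu, Ser and Tyr tRNAs fell (Leu-CAA among them) and 1 rose, 8 with an anticodon beginning with T or A fell and none rose, and 10 with adenosine at 57 fell and 2 rose. Among charged and hydrophobic amino acids, 7 and 11 fell and 1 and 3 rose. At 42oC in WT, 4, 6, 4, 3 and 9 members of these lists rose, in the same order. These counts were the same adjusted over the list alone, except that 3 with adenosine at 57 rose at 42oC in WT.

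In the second set, the A58 signal was nearly gone in the +DM libraries. Ala-GGC-1 fell from 98.0% ± 0.309 in -DM to 0.722% ± 0.0838 in +DM under Ctrl (SD, n = 2 each; log2 odds −12.7 ± 0.249 SE, adjusted p = 1.4e-46) and Ile2-CAT from 94.0% to 0.937%. Leu-TAA fell from 31.2% ± 3.54 to 0.434% ± 0.0555, fMet-CAT from 45.6% ± 4.14 to 0.0833% ± 0.0269 and Arg-ACG from 5.85% ± 0.819 to 0.0840% ± 0.0058. Lys-TTT kept most, at 8.12% ± 0.65 from 84.7% ± 2.84 (−5.98 ± 0.282 SE). Of 49 tRNAs, 45 fell under Ctrl, 44 under EtOH, 46 under 42oC and 42 under H2O, and none rose by edgeR's test. The groups did not overlap for 47 tRNAs under Ctrl, where chance gives 33.3% for 2 libraries against 2. Over all tRNAs the mean share was 36.4% ± 1.5 in -DM and 0.841% ± 0.133 in +DM under Ctrl (SD, n = 2 each). No pool holds both labels, but each label fills 2 pools. The Ctrl libraries of the -DM pools stood at 37.5% and 35.3%, and those of the +DM pools at 0.935% and 0.747%. The loss thus recurred in both +DM pools. This cannot separate the label from anything else that both pools of 1 label share.

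Within the -DM libraries, heat moved A58 both ways, 6 tRNAs up and 10 down of 49. Gly-TCC-1 rose from 29.0% ± 0.994 to 46.5% ± 2.53 (SD, n = 2 each; log2 odds 1.09 ± 0.275 SE, adjusted p = 0.00155), Leu-TAA from 31.2% ± 3.54 to 42.9% ± 2.45 (0.73 ± 0.281 SE, 0.0397) and Cys-GCA-1 from 6.34% to 17.1%, with Gly-CCC, His-GTG and Phe-GAA. Ser-GCT fell from 67.4% ± 0.326 to 47.8% ± 1.57, Gln-CTG-2 from 47.5% ± 3.34 to 29.3% ± 0.817, Gly-GCC from 46.9% ± 5.13 to 29.0% ± 0.535 (−1.11 ± 0.157 SE, 8.09e-08), Asp-GTC from 74.0% to 58.9% and Leu-CAG from 74.1% to 59.7%. fMet-CAT (32.1% against 45.6%, adjusted p = 0.0555) and Arg-ACG (adjusted p = 0.986) passed no threshold. Of the 6 rises, 5 were also called in the 3-library WT set, where 19 of these 49 tRNAs were called higher. Of those 19, 2 went the opposite way here, Leu-CAG and Thr-GGT-1. Across 49 tRNAs both heat effects correlated with rho 0.425 and r 0.434 (permutation p = 0.0026, adjusted 0.0039). Under EtOH and under H2O, Asp-GTC alone was called, falling from 74.0% ± 1.67 to 64.6% ± 1.84 (adjusted p = 0.00381) and to 65.3% ± 0.81 (adjusted p = 0.00969). Leu-TAA (adjusted p = 0.993 and 0.851), fMet-CAT (0.76 and 0.444) and Arg-ACG (0.423 and 0.286) were not called. By limma no tRNA was called in either, with 6 and 4 at an unadjusted p under 0.05 by edgeR. The groups did not overlap for 32, 25 and 23 tRNAs at 42oC, EtOH and H2O, where chance gives 33.3%. The 42oC count was 8 without replicate 1 of 42oC and 10 by limma.

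Position 59 carried a second DM-sensitive signal that did not depend on Trm1L. In 3 glutamate, 3 serine and 1 tyrosine tRNA, the adenosine after A58 was misread while A58 itself was low. In WT under Ctrl the share at A59 was 84.0% ± 0.214 in Glu-CTC-1, 82.1% ± 0.21 in Glu-TTC, 65.0% ± 0.216 in Ser-CGA, 62.7% ± 0.779 in Ser-GGA, 63.3% ± 0.905 in Ser-TGA and 78.5% ± 0.171 in Tyr-GTA (SD, n = 3 each). In Trm1L it stood higher, at 86.4%, 84.2%, 75.9%, 73.6%, 76.8% and 83.0%, though strain and pool cannot be told apart. With +DM it was 1.33% in Glu-CTC-1, 0.849% in Glu-TTC and 0.413% in Ser-CGA, against 87.2%, 86.1% and 84.1% in -DM. These tRNAs, and the sites named in the scan below, were singled out after their values were seen. Thr-TGT had both signals, with 22.3% ± 0.128 at A59 in WT and 27.0% ± 0.289 in Trm1L.

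**Figure D4:**
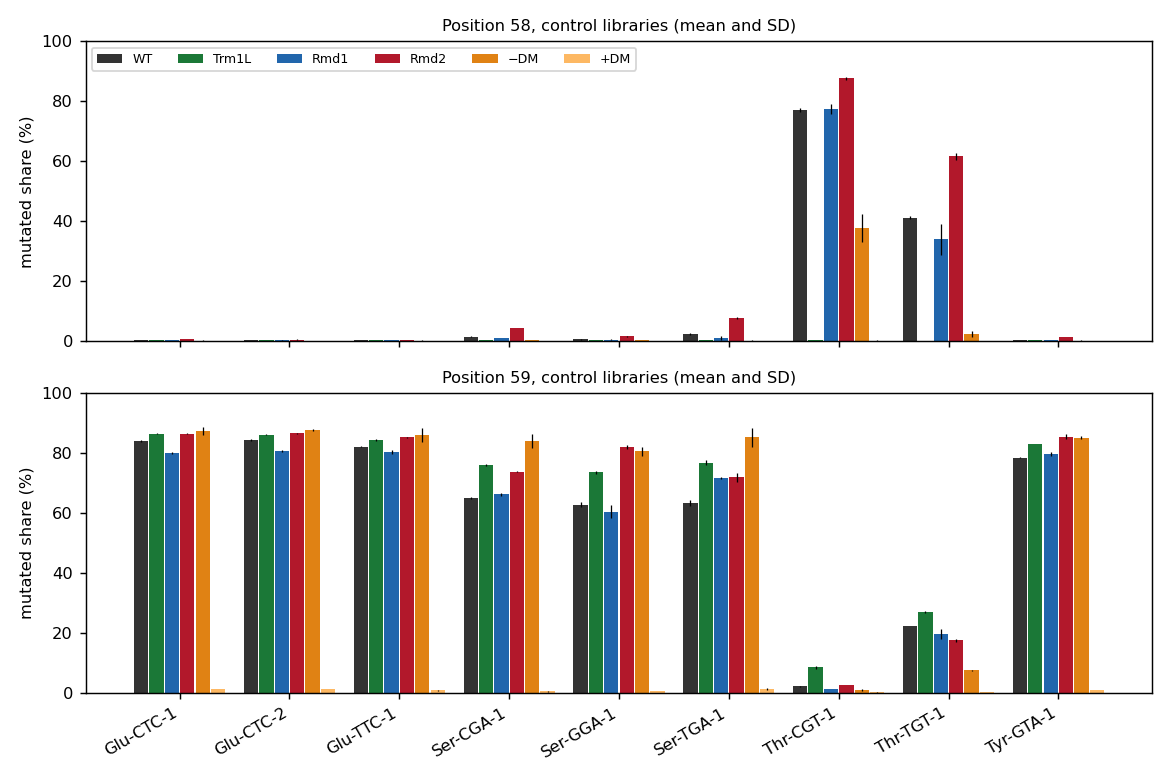
Mutated share (percent, mean and SD over 3 libraries, or 2 for -DM and +DM) under Ctrl at position 58 (top) and position 59 (bottom) of 9 tRNAs in WT, Trm1L, Rmd1, Rmd2, -DM and +DM. Glu, Ser and Tyr tRNAs have low bars at 58 and high bars at 59, which persist in Trm1L (86.4% in Glu-CTC-1) and vanish with +DM (1.33%).

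A scan of 84 positions, 43 at A58 and 41 elsewhere, asked which other sites differed between strains under Ctrl. Of the 41, 6 sites of fMet-CAT entered through 1 library of Trm1L under EtOH and were called in no strain. In Trm1L all 43 sites at A58 fell, while 27 of the 41 others rose and none fell by edgeR's test, with 12 of 19 at position 37 and 9 of 9 at position 59 among them. In Rmd2, 23 of the others rose and 7 fell, and in Rmd1 10 rose and 19 fell. Strain and pool cannot be told apart at these sites either. Cytidine 34 of Ile2-CAT, which bacteria convert to lysidine so that it reads AUA, rose from 12.8% ± 0.257 in WT to 45.7% ± 1.19 in Rmd2 (SD, n = 3 each; log2 odds 2.52 ± 0.0432 SE, adjusted p = 1.27e-26), and stood at 15.9% in Trm1L and 15.7% in Rmd1. Adenosine 37 of Cys-GCA-1 rose from 6.64% ± 0.224 to 16.8% ± 0.132 in Rmd2 and to 16.4% ± 0.918 in Trm1L. Adenosine 34 of Arg-ACG, an inosine in bacteria, was read as another base in 96.7% ± 0.181 of WT reads, and as G in 99.9% of these. Position T8, the 4-thiouridine site of other bacteria, and A9 and A22, m1A sites of some archaea and bacteria, reached 5% in 0 of 51, 29 and 10 tRNAs in WT (medians 0.614%, 0.383% and 0.495%), a count of levels with no test.

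Between -DM and +DM, 35 of 53 scanned sites other than A58 were called, 19 higher and 16 lower with +DM. All 8 at position 59 fell. Guanosine 37 of Leu-CAG, a site of m1G in bacteria, fell from 26.7% ± 1.27 to 4.55% ± 0.228, and that of Leu-GAG from 9.21% ± 0.643 to 2.59% ± 0.0435 (SD, n = 2 each). With +DM, guanosine 57 of Arg-CCG rose from 1.87% to 15.3% ± 1.52. Counting only sites with a share of 10% or more, 5 were higher and 9 lower, which turned the balance, and the count for Rmd1 was 17.

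The abundance of tRNAs in the reads differed between strains under Ctrl, though strain and pool cannot be told apart. In Trm1L 23 of 53 tRNAs were higher and 20 lower than in WT. Ile-GAT rose from 7414 ± 1588 to 28816 ± 2152 CPM (SD, n = 3 each; log2 fold change 1.98 ± 0.136 SE, adjusted p = 4.68e-14), with Cys-GCA-1 (1.96), Pro-GGG (1.76), Arg-CCG (1.72) and Arg-ACG (1.70 ± 0.185 SE, 1.24e-09). Phe-GAA fell by 1.09, Thr-GGT-2 by 0.96, Thr-GGT-1 by 0.95 and the glutamate tRNAs Glu-CTC-2 and Glu-CTC-1 by 0.94 and 0.92 on the log2 scale. Leu-TAA fell by 0.52 (adjusted p = 0.0014), though its libraries overlapped, and fMet-CAT stood at 0.30 (adjusted p = 0.0583). In Rmd1 Thr-CGT rose by 1.42, Gly-TCC-2 and Leu-TAG by 1.36 and Val-GAC by 1.22, while fMet-CAT fell by 1.10 (± 0.147 SE, 1.2e-07), Gln-CTG-1 by 0.95 and Pro-CGG by 0.70. In Rmd2 Arg-CCG rose by 1.22, Ile-GAT by 1.14, Ser-TGA by 1.13 and fMet-CAT by 0.58 (0.000857), and Phe-GAA fell by 1.01, Thr-GGT-1 by 0.89 and Arg-CCT by 0.73. Leu-TAA rose by 0.35 in Rmd2 (adjusted p = 0.0261), with overlapping libraries, and stood at 0.08 in Rmd1 (adjusted p = 0.66). Arg-ACG stood at 0.13 in Rmd1 (0.563) and at 0.28 in Rmd2 (0.155).

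Of 53 tRNAs, 21 were higher and 19 lower in Rmd1, and 24 higher and 17 lower in Rmd2. Library-size scaling gave 17 and 22 in Rmd1, with a shift of the median by −0.10, as DESeq2 did (17 and 22), and DESeq2 gave 17 and 19 in Rmd2, with a shift by −0.14, so that the balance of rises and falls has no firm direction. Without replicate 1 of Rmd1 under Ctrl, 15 were higher and 16 lower. Libraries did not overlap for 46, 38 and 40 tRNAs in Trm1L, Rmd1 and Rmd2, where chance gives 10%. Stress in WT left the share of each tRNA in the reads nearly as it was. A change common to all tRNAs would not show in scaled counts. Ser-TGA rose under EtOH (0.36 ± 0.0837 SE, adjusted p = 0.00872) and Ala-GGC-1 at 42oC (0.19 ± 0.0479 SE, adjusted p = 0.0304), with 6 and 8 tRNAs at an unadjusted p under 0.05. Leu-TAA (adjusted p = 0.633 and 0.598), fMet-CAT (0.866 and 0.787) and Arg-ACG (0.934 and 0.876) were not called. Libraries did not overlap for 12 and 11 tRNAs. DESeq2 called 2 and 0. The EtOH call was lost without replicate 1 or 3 of WT under Ctrl or replicate 2 under EtOH (0 each). The 42oC count was 0 without any 1 replicate of WT under Ctrl or replicate 1 at 42oC, 2 without replicate 2 at 42oC and 3 without replicate 3.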

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

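The treatment effects of the mutants were set against those of WT by interaction terms, and 4 of these tests called tRNAs. A58 moved differently in 7 tRNAs for Trm1L at 42oC, in 16 for Rmd1 under EtOH, in 16 for Rmd1 at 42oC and in 5 for Rmd2 under EtOH. Each stands here because the difference between the strains' effects itself passed the test. For Trm1L, whose A58 lay at background, the difference for the 5 tRNAs that rose in WT follows from the lost signal, and the other 2 moved by under 0.1 points. Reads on the reference sequence that is not a tRNA, which no comparison of the report used, made up 3.1308% ± 1.0044 of the reads in Rmd1 under Ctrl against 1.3743% ± 0.3116 in WT, and 2.7597% ± 0.3417 under EtOH against 2.1229% ± 0.2062 (SD, n = 3 each). These stand here because every Rmd1 library lay above every WT library under Ctrl and EtOH, while at 42oC the libraries overlapped (1.7354% ± 0.7806 against 1.5797% ± 0.3804). The rule looked only for shares above WT. Every Trm1L and Rmd2 library lay below every WT library under EtOH (at most 1.32% and 1.31% against at least 1.93%). The same held at 42oC (at most 1.12% and 1.11% against at least 1.22%). The test of Rmd2 at A59, the test of the base at position 59, the bootstrap interval and all counts over other splits of the samples were chosen only after the results were seen.

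The rise of A58 in Rmd2 under Ctrl was set against a pool-wide change in reading modified bases. Over 31 scanned sites other than A58 with a WT share of 5% or more, the median was 0.2586 on the log2 odds scale (21 up, 10 down), against 1.2359 over 39 sites at A58 (permutation p = 2e-05), which argues against such a change as the whole cause. At A59, where the signal was also lost in the +DM libraries, all 7 sites were higher in Rmd2, with a median of 0.5678 (permutation p = 0.0547 against A58). A difference between pools in reading DM-sensitive adenosines therefore remains open and cannot be told apart from the strain. A candidate biological explanation is that Rmd2 lacks an activity that lowers m1A58, since the series title names m1A erasers, but the labels do not give its gene and no library of another pool holds this strain.

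The lower A58 of Rmd1 under Ctrl went with the lowest read-through of the 4 strains. Sites other than A58 had a median of −0.1798 (11 up, 20 down), beside −0.0919 at A58 (permutation p = 0.427), which is what a pool-wide change in reverse transcription or alignment would give, so that this explanation stays open. Arg-CCG and Gln-CTG-1 rose in the same libraries, and no explanation was tested for these. A difference between the strains in m1A stays among the open explanations, untested by another pool.

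The rise of A58 with heat in WT lay within 1 pool. An older tRNA pool after reduced synthesis may raise m1A in tRNAs that become scarcer, yet the change in abundance and the change at A58 had a Spearman rho of −0.1452 over 51 tRNAs (permutation p = 0.309, 95% bootstrap interval −0.401 to 0.144), which leaves this undecided. Sites other than A58 had a median of −0.01395 (14 up, 17 down) against 0.108 at A58 (permutation p = 0.00182), which argues against a pool-wide change in reading. Single sites other than A58 were still called with heat by edgeR's test. T34 of Glu-TTC rose from 9.86% to 15.9%, as did the base before it, T34 of Gln-TTG, A37 of Cys-GCA-1 and A59 of Thr-TGT. A59 of Ser-CGA fell from 65.0% to 62.5%, as did G37 of Arg-ACG and Gln-TTG. The effect of heat on the enzymes that place or remove m1A stays open as the biological explanation and was not tested.

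For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in 1 split, the real one, the count was reached unless said otherwise. Real counts and the highest of the other splits were 50 and 40, 49 and 40, and 50 and 41 for Trm1L against WT under Ctrl, EtOH and 42oC. They were 34 and 2, 27 and 0, and 30 and 1 for Rmd1, and 50 and 0, 51 and 0, and 51 and 0 for Rmd2. For EtOH and 42oC they were 9 and 0, and 20 and 0 in WT, 26 and 20, and 38 and 21 in Rmd1, 6 and 1, and 29 and 1 in Rmd2, and 2 and 1 in Trm1L under EtOH. In Trm1L at 42oC 2 splits reached the real count of 2 (highest other 2). For abundance they were 43 and 0 in Trm1L, 40 and 5 in Rmd1, 41 and 0 in Rmd2 and 1 and 0 under EtOH, while at 42oC 2 splits reached the real count of 1 (highest other 1). For sites other than A58 they were 27 and 0, 29 and 0, and 30 and 1 in Trm1L, Rmd1 and Rmd2.

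For the differences between strains' effects, 50 splits were drawn with treatment labels reassigned within strains, and after those counts were seen 50 more with strain labels reassigned within treatments. In the first set, 5 splits reached the real 7 for Trm1L at 42oC (highest other 25), 3 the 16 for Rmd1 under EtOH (18), 6 the 16 for Rmd1 at 42oC (34) and 1, the real one, the 5 for Rmd2 under EtOH (3). In the second, 18 reached the 7 (highest other 50), 10 the 16 under EtOH (39), 10 the 16 at 42oC (28) and 9 the 5 (51). For Trm1L under EtOH and Rmd2 at 42oC the real count was 0 by edgeR, which all 50 splits reached in both sets (highest other 2 and 20, then 49 and 51). Neither set shows what equal effects would give, since reassigned labels mix libraries that differ by treatment or by strain. Highest counts of several times the real ones may come from this structure of the samples alone. Whether chance can be excluded for these differences is therefore left open, also for Rmd2 under EtOH.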

How the results depend on the processing

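No alternative setting was chosen after the data were seen (the tests added then are named in flagged.md), and the cause of each change below was not tested. The charging alternatives were not run, since charging was not analysed. The A58 counts for Trm1L, Rmd1 and Rmd2 against WT, for 42oC in WT, Rmd1 and Rmd2 and for +DM moved by no more than 1.5 times under any alternative run, except for the balance of Rmd1 named below. Depth limits the second set most, where a tRNA had as few as 1 read at A58.

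For A58, limma on log2 odds called 3 for EtOH in WT (9 by edgeR), 11 for 42oC in Trm1L (2), 17 and 3 for EtOH in Rmd1 (26) and Rmd2 (6), 1 and 2 for the EtOH difference of Trm1L (0) and Rmd2 (5), and 0, 10 and 0 for EtOH, 42oC and H2O without DM (1, 16 and 1). With deletions counted, the direction turned for Rmd1 against WT under EtOH (28, 17 higher and 11 lower) and EtOH in WT (11, 5 higher and 6 lower). The counts were 5 for 42oC in Trm1L, 10 for EtOH in Rmd2, 4 and 13 for the EtOH and 42oC differences of Trm1L, and 10 and 3 for those of Rmd2. With only the groups compared, they were 15 for EtOH in WT (7 higher and 8 lower, reversed), 0 for 42oC in Trm1L, 3 for EtOH in Rmd1 and 15 in Rmd2. The differences then gave 2 and 4 for Trm1L, 8 and 7 for Rmd1 and 14 and 1 for Rmd2 under EtOH and 42oC. A minimum of 10 reads gave 2 for H2O without DM.

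With the replicate block, 9 were called for 42oC in Trm1L, 1 for the EtOH difference of Trm1L and 2 for the 42oC difference of Rmd2. The replicate block moved no other count by over 1.5 times, and every sample was closest to its own number in 5 of 17 comparisons.

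Of the values of named tRNAs, 9 reversed, in Pro-GGG, Ser-TGA and Arg-ACG. With deletions counted, Pro-GGG and Ser-TGA turned to 0.304 (adjusted p = 0.0001348) and 0.178 (0.1057) in Rmd1 against WT under EtOH, and Ser-TGA to 0.01257 (0.9133) at 42oC. At the most mutated site within 5 nt, which is A59 in Ser-TGA, Ser-TGA was at 0.3919 and 0.3811 in these comparisons. At that site, G57 in Arg-ACG with +DM, Arg-ACG was at 3.299, 3.274, 3.174 and 2.91 under Ctrl, EtOH, 42oC and H2O. In all, 5259 values of named tRNAs kept direction and side of the threshold, 269 lost the call and 19 gained it. Of counts and means, 511 stayed, 88 moved and 11 reversed.

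For abundance, library size only and DESeq2 each gave 39 for Rmd1 (17 higher and 22 lower, reversed). DESeq2 gave 36 for Rmd2 (17 higher and 19 lower, reversed), 2 for EtOH and 0 for 42oC in WT, and library size 2 for EtOH. At a share of 10% or more, the site scan gave 17 for Rmd1 and 14 for DM (5 higher and 9 lower, reversed). Weighted by coverage, the mean share of Trm1L, Rmd1 and Rmd2 under Ctrl differed from WT by −48.678, −5.1788 and 12.688 points, and that under EtOH from Ctrl by 1.0796 in WT and 0.012576 in Trm1L. A minimum of 1000 reads gave −46.384 for Trm1L.

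Leaving out 1 library, the counts ran from 1 to 9 for EtOH in WT, 0 to 2 and 0 to 11 for EtOH and 42oC in Trm1L, 8 to 31 for EtOH in Rmd1, 0 to 7 for EtOH in Rmd2, and 28 to 30 for Rmd1 against WT at 42oC. They ran from 0 to 2 and 2 to 10 for the EtOH and 42oC differences of Trm1L, 9 to 18 and 12 to 26 for those of Rmd1 and 2 to 6 and 0 to 2 for those of Rmd2. Without DM they ran from 0 to 1, 8 to 14 and 0 to 2 for EtOH, 42oC and H2O. For abundance they ran from 31 to 39 for Rmd1, 0 to 1 for EtOH and 0 to 3 for 42oC. The libraries that moved a count by over 1.5 times were as follows. For EtOH in WT, without Ctrl 1, Ctrl 3 and EtOH 3 the count was 1 (reversed, 0 higher), 2 and 3 (reversed, 1 higher). For EtOH in Trm1L it was 0 without Ctrl 2 or 3 or any EtOH library. At 42oC it was 5 without Ctrl 1 and 0, 11 and 4 without 42oC 1, 2 and 3. For EtOH in Rmd1 it was 8 without Ctrl 1 and 17 without EtOH 3, and in Rmd2 1 without Ctrl 1 and 0 without EtOH 3. For Rmd1 against WT at 42oC it was 29 (reversed, 14 higher) without Rmd1 42oC 3. For the EtOH difference of Trm1L it was 2 without its Ctrl 1, and for 42oC 3 without its Ctrl 1 and 2 without its Ctrl 3, WT Ctrl 2 or WT 42oC 1 or 2. For that of Rmd1 under EtOH it was 9 without its Ctrl 1 or EtOH 3 and 10 without WT EtOH 1, and at 42oC 26 without its Ctrl 3. For that of Rmd2 under EtOH it was 3 without its Ctrl 1 or 2, WT Ctrl 3 or any WT EtOH library and 2 without its EtOH 3. At 42oC it was 2 without its Ctrl 3 or WT 42oC 1 and 1 without its 42oC 1. Without DM it was 0 for EtOH without Ctrl 1 or EtOH 2, and 8 for 42oC without 42oC 1. For H2O it was 0 without Ctrl 1 or either H2O library and 2 without Ctrl 2. For the abundance of Rmd1 it was 31 (reversed, 15 higher) without its Ctrl 1. For abundance under EtOH it was 0 without WT Ctrl 1 or 3 or EtOH 2, and at 42oC 0 without any WT Ctrl library or 42oC 1, 2 without 42oC 2 and 3 without 42oC 3.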

Other observations

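The WT libraries of both sets were grown under Ctrl, yet their A58 shares differed for many tRNAs. Of 49 tRNAs, 16 were lower by 10 points or more in the -DM libraries than in the WT set with 3 libraries, and 3 were higher. Gly-TCC-1 stood at 29.0% ± 0.994 against 75.6% ± 0.642, Leu-TAA at 31.2% ± 3.54 against 73.4% ± 0.625 and Thr-TGT at 2.46% ± 1.08 against 41.2% ± 0.406, while Ile2-CAT stood at 94.0% ± 0.745 against 54.3% ± 1.38 (SD, n = 2 and n = 3). Read-through was 20.1% to 23.7% in the -DM libraries and 74.7% to 80.9% in the WT set. These values were compared without a test, since the sets differ in pool, and these tRNAs were picked after their values were seen.

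The test of the base at position 59 was chosen only after the result was seen, as was the bootstrap interval, and the correlation with abundance in Trm1L was fixed before. Among tRNAs with A58, the 27 with adenosine at 59 had a median share of 22.3% in WT under Ctrl and the 14 with guanosine 76.0%, a difference of −53.73 points (permutation p = 0.00046). The 8 with T and the 3 with C stood at medians of 75.6% and 77.8%, and the 27 include the 7 Glu, Ser and Tyr tRNAs with misread A59 that prompted the test, so that it is not independent of them. Reads lost at m1A58 in WT were predicted to raise the tRNAs with high A58 in Trm1L. The change in abundance and the WT share had a Spearman rho of −0.04329 over 52 tRNAs (permutation p = 0.761, 95% bootstrap interval −0.369 to 0.265). The share counts only reads that passed A58, so it need not follow the reads lost there. Whether lost reads caused the abundance changes is therefore left open.

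Some positions of the methionine tRNAs were misread in 5% or more of reads in 1 library or in every library of 1 treatment of the DM set, given with Wilson 95% intervals and without a test. Misread here means any base other than the reference base, whatever its cause, which was not tested. In fMet-CAT, positions 17, 28, 29, 43, 44 and 73 of the reference sequence were misread in 31.02% (30.8% to 31.3%), 30.9% (30.7% to 31.1%), 30.76% (30.52% to 30.99%), 30.81% (30.57% to 31.04%), 30.63% (30.4% to 30.9%) and 25.8% (25.53% to 25.9964%) of reads in replicate 3 of Trm1L under EtOH. Cytidine 41 was misread in 69.9% (67.8% to 71.8%) and 66.6% (64.0% to 69.1%) in the EtOH libraries without DM, in 16.6% (15.7% to 17.4%) and 6.47% (5.99% to 6.98%) in those with DM, and in 10.4% (8.27% to 12.9%) in replicate 1 of H2O without DM. Guanosine 71 was misread in 20.3% (17.7% to 23.2%) and 22.8% (20.3% to 25.5%) without DM and in 27.0% (26.2% to 27.9%) and 24.5% (23.8% to 25.2%) with DM at 42oC, and in 5.38% (5.24% to 5.51%) in replicate 3 of Rmd2 under Ctrl. Guanosine 70 of Met-CAT was misread in 9.21% (8.37% to 10.1%) and 9.46% (8.65% to 10.3%) without DM and in 13.2% (12.7% to 13.8%) and 13.02% (12.6% to 13.5%) with DM at 42oC.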
